A study of Mus musculus with 8 samples.

How the data were processed

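The series measured RNA in single immune cells of the pregnant mouse uterus at embryonic day 7.5. Dams were C57BL6 or Il33cit/cit, a line that the labels describe as lacking IL-33, and every dam was mated with a C57BL6 male. Decidua is the maternal lining around the embryo, and myometrium is the muscle wall of the uterus. Per the labels, each tissue was digested with collagenase, for longer in myometrium than in decidua, treated with an anti-Podoplanin antibody and a dead cell removal kit, and sorted for live CD45.2+ cells. The cells of each genotype carried their own TotalSeq-A hashtag, an antibody with a sequence tag, and both genotypes were pooled in equal parts before each 10x Chromium 3' run.

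The labels describe 8 samples in 4 groups of 2, which are RNA and hashtag libraries of decidua and of myometrium. The files hold 4 matrices, and each combines the RNA and hashtag counts of 1 run. No label, header or feature name ties a matrix to a tissue or a replicate, so the matrices are called library 1 to library 4 after the submitters' numbers, and none was assigned to a tissue. The planned comparisons of decidua with myometrium, and of the genotype difference between tissues, were therefore not run. In the labels several tag numbers are given for the IL-33-deficient dams, whereas the matrices name their 2 tags WT and KO, and these names set the genotype. The number of dams per pool, and whether libraries share dams, is not stated. P-values of the main tests therefore measure how the genotype difference inside a library varies over these 4 libraries, which mix the tissues. Differences between the libraries themselves are taken up by the library block described below. Per-sample columns left unused numbered 0.

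The deposited values are raw UMI counts per gene and barcode, made by the authors with Cell Ranger 6.1.0 and bcl2fastq 2.20.0.422 against mm10 (GRCm38) and restricted to barcodes that their pipeline called as cells. Each matrix has 32285 genes. The files hold 33565 barcodes with 357542788 RNA UMIs. Libraries 1 to 4 had 9040, 7368, 8707 and 8450 barcodes, and 120272739, 57430792, 117651982 and 62187275 UMIs.

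Cells with at least 200 genes and at most 10% mitochondrial counts were kept (32188 cells). Doublets were called with scrublet at an expected rate of 0.06, which marked 2.77%, 2.21% and 2.37% of cells in libraries 1 to 3. In library 4 the automatic threshold of 0.656 marked 0.0123% of cells, so the median threshold of the other libraries, 0.268, was used there and marked 1.94%. Genotypes were assigned with HTODemux of Seurat 5.3.0 (R 4.3.3, positive quantile 0.99). Cells with both tags were left out as doublets, and cells called negative for both were clustered but not compared in the main setting. Of the doublets with both tags, scrublet had called 33.7%, 19.7%, 25.5% and 13.8% in libraries 1 to 4. Doublets of 1 genotype, which the tags cannot show, can therefore remain among the compared cells. Negative cells made up 2.5%, 28.0%, 3.01% and 16.1% of barcodes in libraries 1 to 4. By the ratio rule given below, many carried a tag. It gave library 2 3933 C57BL6 barcodes instead of 1951, and 2935 IL-33-deficient ones instead of 3106. In library 4 it gave 3859 instead of 3864 and 4021 instead of 2831. NK or ILC1-like cells made up 62.5% of clustered negative cells and 48.0% of compared cells. After these steps 26772 cells were compared, of which 12979 were C57BL6 and 13793 IL-33-deficient. The median UMI count per cell was lower in IL-33-deficient than in C57BL6 cells of each library, at 6139 against 6954, 6063 against 6814, 5162 against 7168 and 4654 against 5717 in libraries 1 to 4.

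Counts were scaled to 10000 per cell and logged with scanpy 1.11.5 (Python 3.11.15, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, pandas 2.3.3). Clustering used 3000 variable genes chosen across libraries without readout list members, mitochondrial or ribosomal genes, then 40 principal components, 15 neighbours and Leiden resolution 1.0, with no integration of libraries, random seed 0 and 1 thread. It gave 28 clusters. A cluster took the name of a marker list when its score was at least 1.5, at least 3 markers were raised (log2 difference above 1 over the median cluster, after adding 10 CPM, with a UMI in at least 10% of cells), and its top 10 genes did not point to another list. Names therefore end in "-like". 24 clusters were named and 4 (clusters 5, 11, 20 and 24) kept their numbers. The partition changes with the seed and with rounding of the principal components, and an earlier partition from the same settings without a fixed number of threads, with its gene, list and share results, had been seen before the partition used here was made. A pattern of clusters in library 3 weighed on that earlier partition was dropped, because cluster numbers defined it. Clusterings at seeds 1 and 2 were then added to measure the instability. They gave 29 and 28 clusters, with adjusted Rand indices of 0.694 and 0.778 against seed 0, and 92.5% and 85.4% of cells kept the same class name. Marker lists covered the lymphoid, myeloid and granulocyte types of the uterus together with stroma, fibroblasts, smooth muscle, endothelium, epithelium, trophoblast, erythroid cells and platelets.

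For each class, raw counts were summed per library and genotype where at least 10 cells were present, and a class was tested where at least 3 libraries gave both genotypes. IL-33-deficient was compared with C57BL6 by the edgeR 4.0.16 quasi-likelihood test (TMM, filterByExpr, robust) with the library as block, at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested in the class. The block comes from the labels, which state that both genotypes were pooled in each run. Deviations from the genotype means correlated within libraries at r = 0.864, 0.897, 0.89 and 0.846 across 7704 genes, and each sample correlated best with its own library. The margin was small in places, as C57BL6 cells of library 4 had r = 0.841 with IL-33-deficient cells of library 2. Libraries 1 and 3 correlated at 0.795 and 0.753. Much of these correlations is therefore shared between libraries that resemble each other. Genes are not independent replicates in these correlations. Class shares were tested with edgeR on cell counts, with an exact two-sided sign-flip permutation test beside it, for which the smallest p with 4 libraries is 0.125. DESeq2 1.42.0 with the same block was the second tool. Pseudobulk levels are counts scaled to 1000000 per sum (CPM) given as mean ± SD over libraries, and log2 changes carry a standard error (SE). This SE is the size of the change over the square root of its edgeR F statistic. It comes from a fit that borrows spread across genes or classes, and is not the observed spread between libraries. Intervals of shares are exact binomial at 95%, a count of 0 is taken to allow 3 counts, and both cover counting error only.

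Gene lists were tested in each class with at least 5 tested members by fry and by camera with a preset correlation of 0.01 (limma 3.58.1), adjusted over the lists of the class, with camera at an estimated correlation beside them. The PValue of fry tests whether a list moves 1 way on balance and its PValue.Mixed whether members change in either direction, and neither compares the list with other genes. The 15 lists were type 2 cytokines and IL-33 receptor, alternative activation of macrophages, classical inflammation, type I interferon response, interferon-gamma response, MHC class II presentation, NK cytotoxic granules and ligands, tissue remodelling and angiogenesis, eosinophil and monocyte chemoattractants, resident macrophage programme, lipid-associated macrophage programme, glycolysis and hypoxia, cell cycle, regulatory T cell programme, and immediate-early and heat-shock genes. Named genes were Il33 and Il1rl1, then in each class the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 10 CPM and 1 sign in every library, list members past the threshold, and the 4 most abundant members of a described list. Where no gene of a class passed, the 3 with the smallest p were named. Tests, lists, markers, the naming rule and most alternatives were fixed before the data were examined.

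Alternatives were DESeq2 size factors, DESeq2 itself, no filter on low counts, no replicate block, each library left out in turn, a ratio rule for hashtags (larger tag at least 10 counts and at least 5 times the other plus 1), stricter cell filters (500 genes, 5% mitochondrial), scrublet calls kept, cells thinned to 1000 UMIs, at least 30 cells per sum, Leiden resolutions 0.5 and 2.0, TMM over classes, and shares without neutrophil-like cells. Analyses without genes on chromosomes 18 and 19, and a clustering without the 63 genes called in any class or in all cells together, were also added after the data had been seen. Gene positions came from the GRCm38 annotation and were matched by symbol for 13024 of 13847 tested genes (94.1%). Called genes were counted in windows of chromosomes 18 and 19 chosen after the data had been seen, and for chromosome 18 the count was set against the most extreme window of 15 Mb over all chromosomes in 999 shuffles of the calls, made among located genes tested in the same number of classes. The gene and list tests were run on simulated data with the spread of each class. Of 100 genes planted with a log2 change of 1, 89% were recovered in NK or ILC1-like, 84% in cDC2-like, 67% in macrophage-like and 24% in neutrophil-like cells, with 7.5%, 8.5%, 5.1% and 5.5% of calls false. The same simulations held 100 further genes with a log2 change of 2 and a planted list of 12 genes. With so many changes an adjusted p passes more easily than in the real data, where at most 30 genes per class were called. These rates can therefore overstate the recovery of real changes. Shares were simulated apart, with a fixed spread, no differences between libraries and a fold of 2 planted in macrophage-like cells only. Of these planted shares 60% were recovered in 50 simulations. Real shares differed between libraries, as with gamma-delta T cell-like cells at 0.613% to 9.92% of C57BL6 cells. The power of the share tests on the real data was therefore not measured.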

Results

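The data are single-cell transcriptomes of CD45.2+ immune cells from the uterus of pregnant mice at embryonic day 7.5, taken from C57BL6 dams and from IL-33-deficient dams that lack this alarm cytokine of stromal cells. The labels list 2 RNA libraries of decidua and 2 of myometrium, each with a hashtag library. The 4 matrices held 57430792 to 120272739 UMIs, and the sums per library and genotype held 15378810 to 58536731 UMIs. The comparison that the files allow is between genotypes inside each library, and it covers 12979 C57BL6 and 13793 IL-33-deficient cells. All values below are IL-33-deficient against C57BL6, over n = 4 libraries unless stated otherwise.

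Natural killer (NK) or ILC1-like cells were the most numerous class with 12859 compared cells, and they carried Gzmb, a cytotoxic granule protease, at 1498 to 5806 CPM over the libraries. B cell-like (2241 cells), classical monocyte-like (2131), T cell-like (1877), cDC2-like (1179), gamma-delta T cell-like (1083), neutrophil-like (1075), macrophage-like (858) and cDC1-like (669) cells followed, cDC1 and cDC2 being types of conventional dendritic cell. Leading genes were C1qa, C1qb and Apoe in the macrophage-like cluster, Chil3, Lyz2 and Ly6c2 in the classical monocyte-like cluster, and Cd209a, Mgl2 and Clec10a in the cDC2-like cluster. Clusters 5, 11, 20 and 24 held 1036, 274, 409 and 170 compared cells and stayed unnamed. Clusters 5 and 11 came closest to the NK or ILC1 markers, cluster 20 (Cxcr6, Rora) to the gamma-delta T cell markers and cluster 24 (Ifi27l2a, Lst1) to the classical monocyte markers.

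Il33 itself (ENSMUSG00000024810) was close to absent from these sorted cells, with 4 UMIs in 12979 C57BL6 cells and 2 UMIs in 13793 IL-33-deficient cells. Libraries 1 and 3 had 0 UMIs in either genotype, where 0 allows up to 0.0512 to 0.0655 CPM, so a difference between genotypes was not detectable at this depth. Whether the targeted allele still gives 3' tags is not stated in the labels. Its receptor gene Il1rl1 (ENSMUSG00000026069, chromosome 1, 40404864 to 40465418 in GRCm38) had 644 UMIs in C57BL6 and 710 in IL-33-deficient cells. In libraries 2 and 4 mast cell-like cells held Il1rl1 at 1487 to 2269 CPM and ILC2-like cells at 878 to 905 CPM. Over all cells its level in C57BL6 was 0.294, 11.7, 0.41 and 14.5 CPM in libraries 1 to 4, and in IL-33-deficient cells 0.373, 16.8, 1.33 and 13.7 CPM. The change of Il1rl1 did not pass (log2 change 0.49 ± 0.26 SE, edgeR adjusted p = 0.744, higher in 3 of 4 libraries).

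In cDC2-like cells Nfkbia, Nfkbiz, Icam1 and Nfkbid were lower and Klf4 was higher in IL-33-deficient dams, and no list of NF-kappa-B genes was tested. Nfkbia (ENSMUSG00000021025, chromosome 12, 55489409 to 55492647), the inhibitor that NF-kappa-B itself induces, fell from 773 ± 166 to 284 ± 102 CPM (SD), a log2 change of -1.47 ± 0.10 (SE, edgeR adjusted p = 1.4e-09). Nfkbiz (ENSMUSG00000035356), a related nuclear regulator, fell from 554 ± 400 to 191 ± 133 CPM (log2 change -1.49 ± 0.12, edgeR adjusted p = 2.37e-07). Icam1 (ENSMUSG00000037405), an adhesion molecule gene, fell from 192 ± 109 to 64.1 ± 30.8 CPM (log2 change -1.55 ± 0.15, edgeR adjusted p = 5.3e-05). Nfkbid, a further member of the inhibitor family, fell from 141 ± 69.6 to 71.9 ± 30.8 CPM (log2 change -0.96 ± 0.13, edgeR adjusted p = 0.000244). Klf4, a transcription factor gene of myeloid cells, rose from 225 ± 41.8 to 339 ± 58.2 CPM (log2 change 0.60 ± 0.09, edgeR adjusted p = 0.00133). Each of these 5 genes moved in its direction in 4 of 4 libraries, but the rule for naming the largest changes required this. Of their calls only that of Klf4 ended without 1 library (library 2, edgeR adjusted p = 0.0565). None of the 5 passed without the library block, where edgeR gave Nfkbia an adjusted p of 0.614. In clusterings at seeds 1 and 2 Nfkbia, Nfkbiz and Icam1 kept their calls, Tnf did not at seed 1 (0.133) and Egr1 at neither (0.519 and 0.163). With thinned cells Klf4 and Nfkbid were not called (0.201 and 0.368).

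Of 11 tested members of the classical inflammation list in cDC2-like cells, Nfkbia and Tnf fell, 0 rose and 9 did not pass, and 9 were lower when adjusted over the list alone. Tnf, the cytokine gene, fell from 72.9 ± 44.7 to 29.2 ± 15.5 CPM (log2 change -1.27 ± 0.20, edgeR adjusted p = 0.00876), but not under the ratio rule for hashtags (0.0848). Il1b, the most abundant member, was at 2830 ± 839 and 1879 ± 1030 CPM (log2 change -0.69 ± 0.13) without passing (edgeR adjusted p = 0.171). Cxcl2 (-0.61, edgeR adjusted p = 0.606) and Ccl4 (-0.26, edgeR adjusted p = 0.656) did not pass either. The median change was -0.72, 10 of 11 members lay below 0, and the median lay below 0 in 4 of 4 libraries. The list moved down by fry (adjusted p = 0.045) and camera (adjusted p = 1.66e-22), with an adjusted p = 0.0383 with an estimated correlation. Leaving out library 1, 2, 3 or 4 ended the fry call (adjusted p = 0.304, 0.155, 0.353 and 0.281), as did leaving out the library block (0.0866) and clustering at seed 1 (0.0589).

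Of 14 immediate-early and heat-shock genes in cDC2-like cells, Jun and Egr1, which encode early-response transcription factors, fell (log2 change -0.39 and -0.70, edgeR adjusted p = 0.0375 and 0.00284), 12 did not pass and 6 were lower when adjusted over the list alone. Among abundant members, Fos and Atf3 had log2 changes of 0.10 and 0.08 and Junb and Zfp36 of -0.20 and -0.23, none past the threshold. Their median was -0.19 (fry adjusted p = 0.255, adjusted p = 0.196 with an estimated correlation). Jun was not called without library 2 or 4, under the ratio rule, with thinned cells or at seed 1 (edgeR adjusted p = 0.431, 0.188, 0.0531, 0.161 and 0.0857) or by DESeq2 (0.12), and Egr1 not under the ratio rule (0.0847). Irf1, an interferon-induced transcription factor gene, fell from 145 ± 30 to 98.4 ± 25.4 CPM (log2 change -0.57 ± 0.11, edgeR adjusted p = 0.0119) but not without library 2 or 4 (0.174 and 0.184), with thinned cells (0.086) or by DESeq2 (0.24). The interferon-gamma list around it had a median of -0.42 and did not pass fry (adjusted p = 0.612). MHC class II genes were abundant and none passed, with Cd74 at 18380 ± 3889 and 18910 ± 4392 CPM (log2 change 0.04, edgeR adjusted p = 1).

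In all, 6 genes rose and 24 fell among 7910 tested in cDC2-like cells (555 C57BL6 and 624 IL-33-deficient cells), and DESeq2 called 22, of which 15 were shared. Mir155hg, the host transcript of miR-155, fell from 37.2 ± 22.6 to 9.16 ± 6.61 CPM (log2 change -2.16 ± 0.33, edgeR adjusted p = 0.0119), a call that ended without library 2 (0.382) and under the ratio rule (0.0511). The T cell receptor gene Trbc2, which cDC2 cells should lack, rose from 6.82 ± 3.98 to 32.9 ± 22 CPM (log2 change 2.08 ± 0.30, edgeR adjusted p = 0.000735). The neutrophil genes S100a8 and S100a9, a sign of RNA from other cells, differed by log2 0.77 ± 1.65 and 0.63 ± 1.66 (SE) in the same sums, with means of -0.46, -2.62, 5.70 and 2.33 in libraries 1 to 4. The class count of 30 was 18 without library 2, 70 without library 3, 14 with cells thinned to 1000 UMIs and 1 without the library block.

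**Figure D1:**
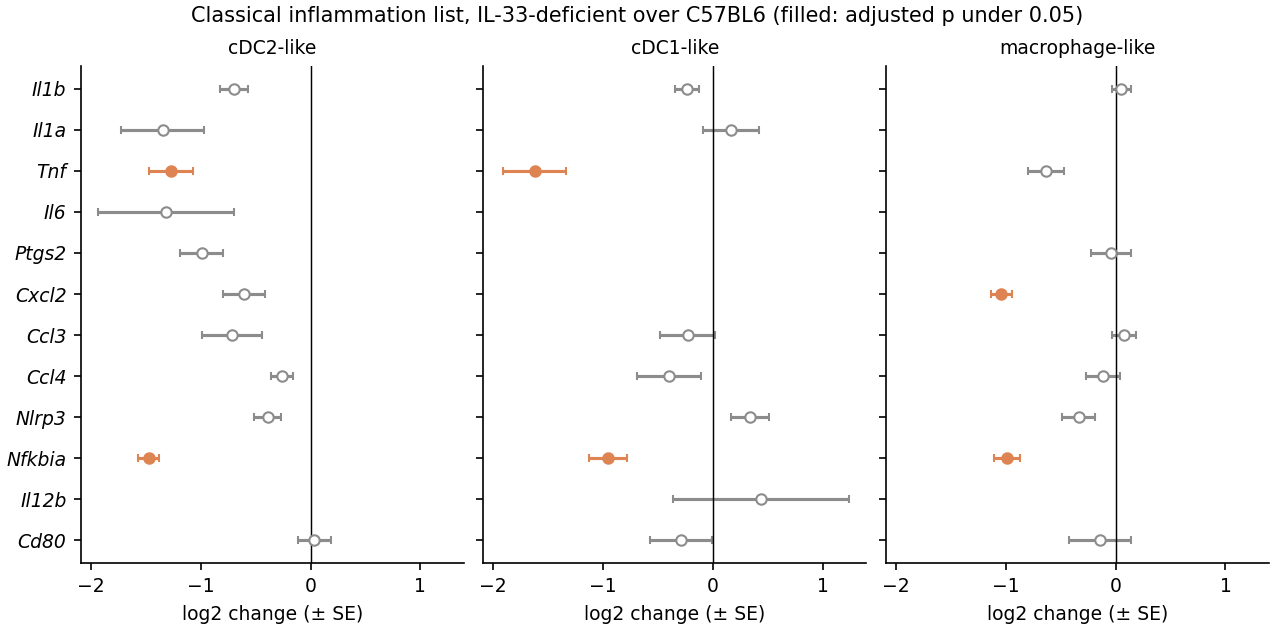
Log2 change of the tested genes of the classical inflammation list in cDC2-like, cDC1-like and macrophage-like cells over 4 libraries. Bars are the SE from the edgeR fit, and filled points have an edgeR adjusted p under 0.05. Nfkbia lay at -1.47, -0.96 and -0.99 in the 3 classes.

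In cDC1-like cells (379 and 290 cells) 7 genes rose and 5 fell among 6386 tested. Myof (ENSMUSG00000048612, chromosome 19, 37899036 to 38043577), which encodes a membrane repair protein, rose from 32.7 ± 19.9 to 100 ± 16.1 CPM (log2 change 1.48 ± 0.18, edgeR adjusted p = 1.56e-05), and no single library ended this call. Ier3, a stress-induced survival gene, fell from 210 ± 125 to 129 ± 80 CPM (-0.67 ± 0.12, edgeR adjusted p = 0.00262). Tnf fell from 28.5 ± 13.8 to 9.51 ± 7 CPM (-1.62 ± 0.29, edgeR adjusted p = 0.00316) and Nfkbia from 149 ± 76.5 to 75 ± 23.3 CPM (-0.96 ± 0.17, edgeR adjusted p = 0.0207). Timd4, a receptor gene for apoptotic cells, rose from 25.6 to 55.4 CPM (1.10 ± 0.20, edgeR adjusted p = 0.00395). Tnf was not called without library 2 (edgeR adjusted p = 0.0705), Nfkbia not without library 2 or 4 (0.169 and 0.53) and Timd4 not without library 4 (0.999), and DESeq2 called none of these 3 (adjusted p = 0.767, 0.145 and 1) and not Ier3 (0.114). The stricter cell filter ended the call of Nfkbia (0.193). Of 9 inflammation genes these 2 fell, 7 did not pass, and the same number was lower when adjusted over the list alone. Il1b, the most abundant, had a log2 change of -0.24 (edgeR adjusted p = 1). The list median was -0.24, and fry did not pass in 1 direction (adjusted p = 0.137) but did for changes in either direction (0.00999), beside camera (0.000262) and an adjusted p = 0.112 with an estimated correlation. The edgeR count of 12 was 23, 19, 28 and 6 without libraries 1 to 4, 3 by DESeq2, 1 without the library block and 0 with thinned cells.

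In macrophage-like cells (494 and 364 cells) 3 genes rose and 7 fell among 6995 tested, and DESeq2 called 10, of which 6 were shared. The neutrophil-attracting chemokine gene Cxcl2 (ENSMUSG00000058427, chromosome 5, 90903899 to 90905938) fell from 1336 ± 295 to 661 ± 192 CPM (log2 change -1.04 ± 0.09, edgeR adjusted p = 5.75e-06). The phosphatase gene Dusp2 fell from 198 ± 67.4 to 88.7 ± 12.8 CPM (-1.11 ± 0.15, edgeR adjusted p = 0.00088), and Nfkbia from 440 ± 70 to 223 ± 44.7 CPM (-0.99 ± 0.12, edgeR adjusted p = 0.000202). Nfkbiz fell from 507 ± 236 to 257 ± 56.6 CPM (-0.90 ± 0.13, edgeR adjusted p = 0.00457), but not without library 2 or 4 (0.315 and 0.0885). Without the library block Cxcl2 had an edgeR adjusted p of 1 and Nfkbia of 0.93, whereas no single library ended either call. Of 9 inflammation genes 2 fell, 7 did not pass and 3 were lower when adjusted over the list alone, with a median of -0.14. Il1b differed by 0.05 (edgeR adjusted p = 0.986). Fry did not pass for 1 direction (adjusted p = 0.117) but did for changes in either direction (0.00105 for PValue.Mixed), beside camera (1.54e-06) and an adjusted p = 0.128 with an estimated correlation. With thinned cells Dusp2, Nfkbia and Nfkbiz were not called (edgeR adjusted p = 0.178, 0.127 and 0.127). At seed 2 of the clustering Nfkbia and Nfkbiz were not called (0.472 and 0.255), whereas Cxcl2 and Dusp2 were at both seeds. The class count of 10 was 5 without library 2, 1 with thinned cells and 1 without the library block.

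Of 7 tested alternative activation genes in macrophage-like cells Mgl2 and Arg1 rose, 5 did not pass, all 7 lay above 0 and 4 were higher when adjusted over the list alone. Mgl2 (ENSMUSG00000040950, chromosome 11, 70130125 to 70137542), a lectin gene of alternatively activated macrophages, rose from 80.6 ± 18.3 to 159 ± 4.48 CPM (log2 change 1.00 ± 0.15, edgeR adjusted p = 0.00273), though not without library 2 (0.206) or with thinned cells (0.127). Mgl2 is also a leading gene of the cDC2-like cluster, where it was at 397 ± 144 CPM in C57BL6 cells. Arg1, the arginase gene, rose from 14.1 ± 9.71 to 51.8 ± 60.3 CPM (1.71 ± 0.30, edgeR adjusted p = 0.0149), a call that ended without library 2 or 4 (0.0637 and 0.0721), by DESeq2 (0.693) and in clusterings at seeds 1 and 2 (1 and 0.48). Library 1 carried the Arg1 mean with 142 CPM against 12.6 to 29.5 in the other IL-33-deficient samples, and without library 1 the gene was not tested. The median was 0.75 (fry adjusted p = 0.129, 0.0376 for changes in either direction, camera 3.1e-08, adjusted p = 0.128 with an estimated correlation). Of 9 MHC class II genes all lay above 0 and none passed over all genes, although 8 passed when adjusted over the list alone. Cd74 was at 10260 ± 875 and 15350 ± 2527 CPM (log2 change 0.57 ± 0.10, edgeR adjusted p = 0.144) and H2-Aa at 4304 ± 656 and 6261 ± 617 CPM (0.55 ± 0.10, 0.0736), and the list median was 0.53 (fry adjusted p = 0.2, camera 8.43e-17, adjusted p = 0.189 with an estimated correlation).

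Gamma-delta T cell-like cells (342 and 741 cells) had 3 genes higher and 3 lower among 5764 tested, and DESeq2 called 2, both shared. AA467197, a gene model among the 10 leading genes of an NK or ILC1-like cluster at resolutions 0.5 and 2.0, rose from 9.04 ± 8.61 to 58.1 ± 38.6 CPM (log2 change 2.69 ± 0.45, edgeR adjusted p = 0.00632), which DESeq2 did not call (0.056) and which was not tested without library 2 or 4. The small GTPase gene Gem (ENSMUSG00000028214) rose from 204 ± 94.5 to 429 ± 152 CPM (log2 change 1.17 ± 0.15, edgeR adjusted p = 0.000108), with an adjusted p of 0.0556 without library 4. Ly6a, the gene of the surface protein Sca-1, rose from 194 ± 133 to 377 ± 214 CPM (1.04 ± 0.18, edgeR adjusted p = 0.0172), but not without library 1 or 4 (0.232 and 0.433), with scrublet calls kept (0.0644), with thinned cells (0.0708), at seed 1 (0.0974) or by DESeq2 (0.123). Areg, which encodes the tissue repair factor amphiregulin, was at 599.7 ± 379 and 971 ± 655 CPM in these cells and did not pass (0.71 ± 0.43, edgeR adjusted p = 1, higher in 3 of 4 libraries). Icos, a costimulatory receptor gene, was at 1139 ± 202 and 1489 ± 325 CPM (0.38 ± 0.10, edgeR adjusted p = 0.245). The class count of 6 was 14 without library 3, 1 without library 4 and 1 without the library block.

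T cell-like cells (769 and 1108 cells) had 0 genes higher and 5 lower among 6535 by edgeR, with 285 at an unadjusted p under 0.05, and DESeq2 called 1. Areg fell from 56.7 ± 43.6 to 25.8 ± 16.1 CPM (log2 change -1.09 ± 0.21, edgeR adjusted p = 0.0454), a call that ended without library 1 or 2 (0.999 and 0.0618). Ikzf2, the gene of the transcription factor Helios, fell from 132 ± 23 to 73.2 ± 34 CPM (-0.85 ± 0.16, edgeR adjusted p = 0.0454), but not without library 2, 3 or 4 (0.0618, 0.0654 and 0.165). Under the ratio rule, the stricter filter, seeds 1 and 2 and without chromosomes 18 and 19 neither gene was called (0.0564 to 0.193 for Areg, 0.0565 to 0.999 for Ikzf2), nor by DESeq2 (1 and 0.723). All 11 type I interferon genes lay below 0 in T cell-like cells (median -0.53, fry adjusted p = 0.503), none passed and 6 were lower when adjusted over the list alone, such as Ifit1 (-0.71 ± 0.17, edgeR adjusted p = 0.208). In library 2 the larger T cell-like cluster was cluster 15 (Trac, Cd5, Cd6) in C57BL6 cells with 3.06% of cells, and cluster 10 (S1pr1, Il7r, Ccr7) in IL-33-deficient cells with 3.22%. The edgeR count of 5 was 1, 2 and 2 without libraries 2, 3 and 4, and 0 without the library block, where Mpp7 had an adjusted p of 0.0766.

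B cell-like cells (1185 and 1056 cells) had 1 gene higher and 4 lower among 5623 tested. Isg15, a ubiquitin-like interferon-induced gene, fell from 56.8 ± 50.9 to 32.3 ± 27.7 CPM (log2 change -0.81 ± 0.18, edgeR adjusted p = 0.0277). Ifit3 fell from 54.5 ± 67.9 to 18 ± 21.7 CPM (-1.57 ± 0.21, edgeR adjusted p = 2.97e-07) on 2 of 4 libraries, and it lies on chromosome 19 near Il33. DESeq2 called neither Isg15 nor Ifit3, each at an adjusted p of 1, and neither was tested without library 1 or 3. Isg15 was not called with the stricter cell filter or with thinned cells (edgeR adjusted p = 0.426 and 0.362). Rhob, a small GTPase gene, rose from 75.4 ± 31.3 to 120 ± 33.2 CPM (0.61 ± 0.14, edgeR adjusted p = 0.0294), but not without library 1 or 3 (0.064 and 0.186), with the stricter cell filter (0.761), with thinned cells (0.318) or by DESeq2 (1). Of 10 type I interferon response genes these 2 fell, 8 did not pass, and 6 were lower when adjusted over the list alone. Ifi27l2a, the most abundant, was at 614 ± 239 and 489.8 ± 197 CPM (-0.31 ± 0.07, edgeR adjusted p = 0.0601). All 10 lay below 0 with a median of -0.46 (fry adjusted p = 0.044, camera 9.77e-12), but an adjusted p = 0.0887 with an estimated correlation and fry adjusted p = 0.0867 without library 4. Interferon-gamma response genes had none of 8 called with all 8 below 0 and a median of -0.22 (fry adjusted p = 0.044, camera 0.0166, adjusted p = 0.124 with an estimated correlation), and did not pass without library 1, 2 or 3 (fry adjusted p = 0.564, 0.13 and 0.154). MHC class II genes such as Cd74 (0.02, edgeR adjusted p = 0.988) did not pass. The edgeR count of 5 was 17, 3 and 12 without libraries 2, 3 and 4, and 0 without the library block with an adjusted p of 0.87 for the type I interferon list by fry.

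NK or ILC1-like cells (6809 and 6050 cells) had 1 gene higher and 10 lower among 12208 tested, and DESeq2 called 21, of which 11 were shared. Npc1 (ENSMUSG00000024413, chromosome 18, 12189694 to 12236506), a cholesterol transporter gene, fell from 38.6 ± 12.3 to 10.9 ± 3.45 CPM (log2 change -1.82 ± 0.08, edgeR adjusted p = 1.49e-05). Ide, which encodes the insulin-degrading enzyme, fell from 86.2 ± 7.84 to 55.4 ± 8.21 CPM (-0.65 ± 0.06, edgeR adjusted p = 0.00437), though not without library 2 (0.069). The receptor kinase gene Grk5, on chromosome 19, rose from 7.37 ± 4.59 to 19 ± 8.37 CPM (1.5 ± 0.14, edgeR adjusted p = 0.00437), though not without library 1 (0.121). None of the 12 granule and ligand genes passed, among them Gzmd at 7521 ± 7612 and 7241 ± 8814 CPM (-0.27 ± 0.23, edgeR adjusted p = 1), and their list median was -0.11 (fry adjusted p = 0.879). Spp1, the osteopontin gene, differed by -0.07 ± 0.08 and the angiogenic factor gene Vegfa by 0.11 ± 0.13. The class pools several clusters whose shares differed between the genotypes of some libraries. Cluster 13 made up 2.09% of C57BL6 and 8.48% of IL-33-deficient cells in library 3, and cluster 12 made up 0.85% and 4.83% in library 2. Over the libraries neither share passed (edgeR adjusted p = 0.865 for each). The class count of 11 was 25, 6 and 7 without libraries 1, 2 and 3, 1 without the library block and 3 without chromosomes 18 and 19.

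Classical monocyte-like cells (948 and 1183 cells) had 2 genes higher and 3 lower. Colec12 (ENSMUSG00000036103, chromosome 18, 9707648 to 9877995), a scavenger receptor gene, rose from 1.81 ± 0.6 to 39.8 ± 16.8 CPM (log2 change 4.62 ± 0.32, edgeR adjusted p = 2.18e-11) and passed without any 1 library and without the library block. Rbbp8, a DNA repair gene on chromosome 18, fell from 61.9 ± 9.82 to 29.8 ± 2.48 CPM (-1.11 ± 0.16, edgeR adjusted p = 0.000169), but not with thinned cells (0.477). Of 10 inflammation genes in these cells 0 passed and 6 lay above 0 (median 0.03, fry adjusted p = 0.852), and Il1b differed by 0.03 ± 0.08 (edgeR adjusted p = 1). The class count of 5 was 8, 57 and 8 without libraries 1, 3 and 4. Rises outnumbered falls without library 3 (43 and 14) and without the filter on low counts (17 and 10). In cluster 5 (415 and 621 cells) the granzyme gene Gzme rose from 20.2 ± 26.3 to 132 ± 222 CPM (2.49 ± 0.36, edgeR adjusted p = 0.000236, higher in 3 of 4 libraries), against 148 to 6892 CPM in NK or ILC1-like cells over the libraries, and AC149090.1 fell. Library 1 carried the Gzme mean with 461 CPM against 0.896 to 63.3 in the other IL-33-deficient samples, and without library 1 or 3 the gene was not tested. For Gzme DESeq2 gave an adjusted p of 1, AC149090.1 was not called without library 4 (edgeR adjusted p = 0.736), and the cluster 5 count of 2 was 4 without library 1. Neutrophil-like cells had 1 called gene, Mpp7, and 4 without library 3, while their Il1b was at 16450 ± 2475 and 17560 ± 2279 CPM (0.10 ± 0.17, edgeR adjusted p = 0.955).

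Mature DC-like cells (79 and 62 cells) had 0 genes called among 2381 by edgeR and 0 by DESeq2, with 98 at an unadjusted p under 0.05. Their smallest p belonged to Myof (8.65 to 101 CPM, log2 change 3.36 ± 0.62, edgeR adjusted p = 0.175), Nfkbiz (-1.52 ± 0.36, 0.662) and AC149090.1 (-1.35, 0.662), which did not pass. The mature DC-like count by edgeR was 1 without library 2, 3 or 4. Non-classical monocyte-like cells (252 and 242 cells) had 0 called among 3635 by edgeR and 0 by DESeq2, with 137 at an unadjusted p under 0.05. Hspa1b, a heat-shock gene (1.41 ± 0.28), Gm26917 (-1.15 ± 0.24) and the chemokine gene Cxcl10 (0.98 ± 0.21) had their smallest p (edgeR adjusted p = 0.223 for each).

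Some genes moved alike in many classes. Mpp7 (ENSMUSG00000057440, chromosome 18, 7347962 to 7626889 in GRCm38), a gene of cell polarity, lay lower in 9 of the 9 classes that tested it and passed in 8. Its log2 changes ran from -6.96 ± 0.31 in cDC2-like cells (75.6 ± 18.7 to 0.535 ± 0.428 CPM, edgeR adjusted p = 1.55e-12) to -1.57 in cluster 5, where it did not pass (0.0524). In NK or ILC1-like cells Mpp7 fell from 38.2 ± 4.82 to 10.5 ± 1.3 CPM (-1.85 ± 0.10, edgeR adjusted p = 4.71e-05). Wdfy1, an endosomal adaptor gene on chromosome 1 (79702262 to 79776143), lay higher in 7 of 7 classes and passed in 3, by 1.07 to 1.93, and in classical monocyte-like cells it was not called without library 1 (edgeR adjusted p = 0.217) or by DESeq2 (0.282). Mid1, a ubiquitin ligase gene on chromosome X, fell in 3 of 3, though in cDC2-like cells not without library 2 or 4 (edgeR adjusted p = 0.209 and 0.249) and in macrophage-like cells not without library 3 or 4 (0.127 and 0.2), where it was not tested without library 2, and DESeq2 called it in neither class (0.217 and 0.664). The unlocated gene models AC149090.1 and Gm47283 lay lower in 11 of 11 and 9 of 9 classes and passed in 6 and 4. Some of these calls ended under other settings. AC149090.1 was not called in T cell-like cells without library 3 or at seeds 1 and 2 (edgeR adjusted p = 0.841, 0.0564 and 0.106). Without library 3 it was not called in classical monocyte-like cells (0.123), nor was Gm47283 in B cell-like cells (0.524). Altogether 10 genes were called in more than 1 class, in 35 calls, among them Nfkbia, which was lower in 9 classes and higher in 3.

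The positions of called genes were uneven. Within 10 Mb of Il33 on chromosome 19 (19925113 to 39960718 in GRCm38) lay 5 of the 61 located called genes (8.2%) and 85 of the 13024 located tested genes (0.653%), an odds ratio of 14.4 (95% interval 4.38 to 36.9, Fisher's exact test, two-sided p = 4.69e-05). They were Ide, Ifit3, Myof, Pip5k1b and Tjp2. The first 15 Mb of chromosome 18 held 6 of 61 (9.84%) against 44 of 13024 (0.338%). Because this window was drawn around called genes, the calls were shuffled among genes tested in as many classes, and none of the shuffles held a window of 15 Mb as extreme anywhere in the genome (permutation p = 0.001). The genes were Colec12, Map3k8, Mpp7, Npc1, Rbbp8 and Wac. Both windows, their widths, the shuffling and the genes named for them were chosen after the values were seen, and genes called in several classes entered once.

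**Figure D2:**
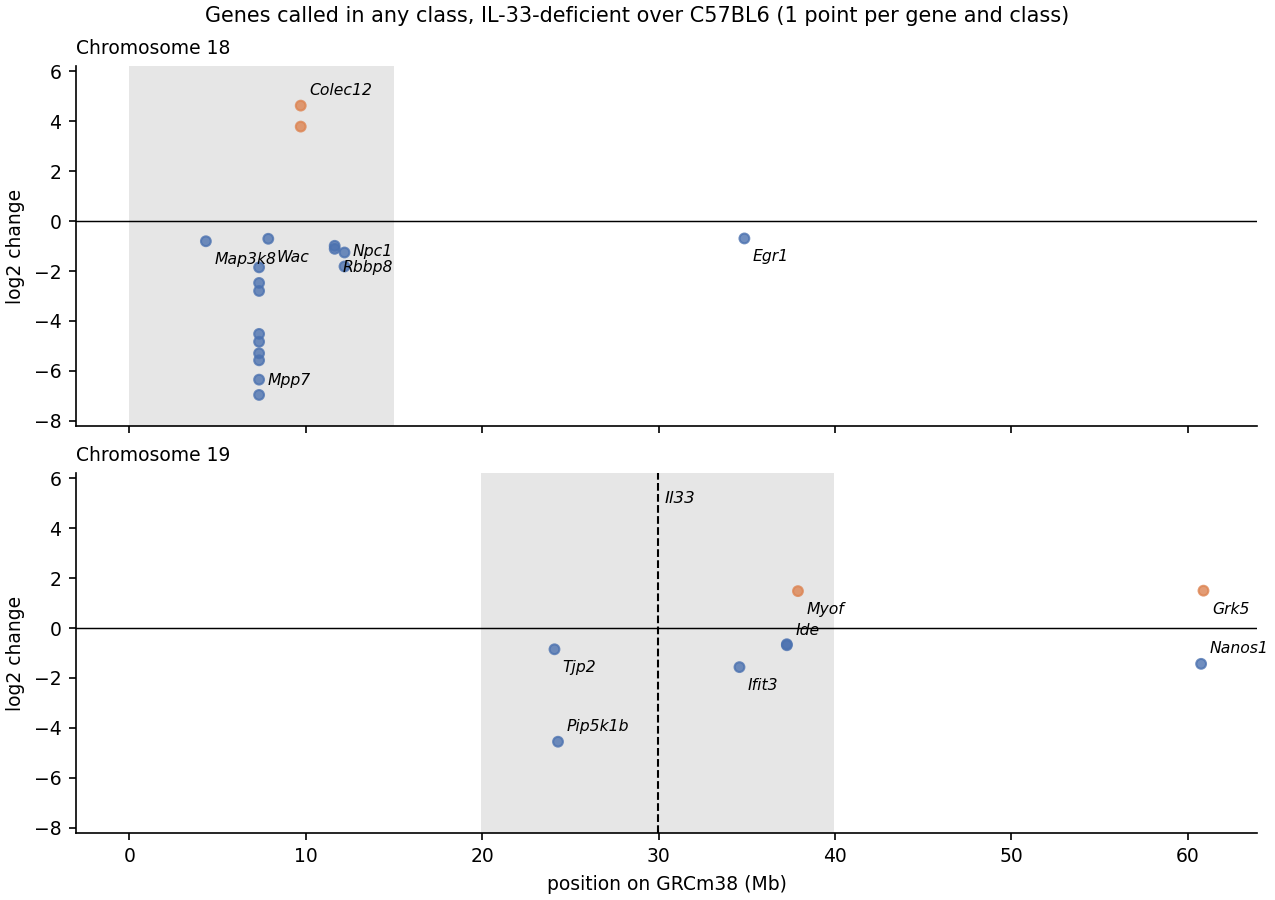
Log2 change of called genes on chromosomes 18 and 19 against their position in Mb (GRCm38), with 1 point per gene and class (all cells included), shaded windows and a dashed line at Il33. Mpp7 has points from -6.96 to -1.85, and Colec12 lies at 3.78 and 4.62.

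Summed over all cells of a library and genotype, 1 gene rose and 6 fell among 13830, with 883 at an unadjusted p under 0.05. Tjp2, a tight junction gene on chromosome 19, fell from 19 ± 1.6 to 10.6 ± 1.39 CPM (log2 change -0.85 ± 0.08, edgeR adjusted p = 0.0355), and Ide from 74.5 ± 7.1 to 46.4 ± 6.16 CPM (-0.69 ± 0.07, edgeR adjusted p = 0.0387). Mpp7 (-2.48), Npc1 (-1.26) and Gm47283 (-0.83) fell, as did Mid1 (-2.16), and Colec12 (3.78) rose, the last 2 named after their values were seen. Without library 3 the edgeR count was 0, and Mpp7 had an adjusted p of 0.246 and Npc1 of 0.0749, and without library 2 Mpp7 had 0.0827. Without libraries 1, 2 and 4 the count was 11, 1 and 4, DESeq2 called 54, of which 7 were shared, and 1 gene passed without chromosomes 18 and 19. Tjp2 and Gm47283 lost their calls without any 1 library (edgeR adjusted p = 0.0587, 0.0575, 0.247 and 0.343 for Tjp2 and 0.199, 0.0524, 0.247 and 0.343 for Gm47283 without libraries 1 to 4), and Ide without library 2, 3 or 4 (0.0761, 0.247 and 0.343). Without the library block 1 gene passed, Mpp7 with an edgeR adjusted p of 0.0296.

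**Figure D3:**
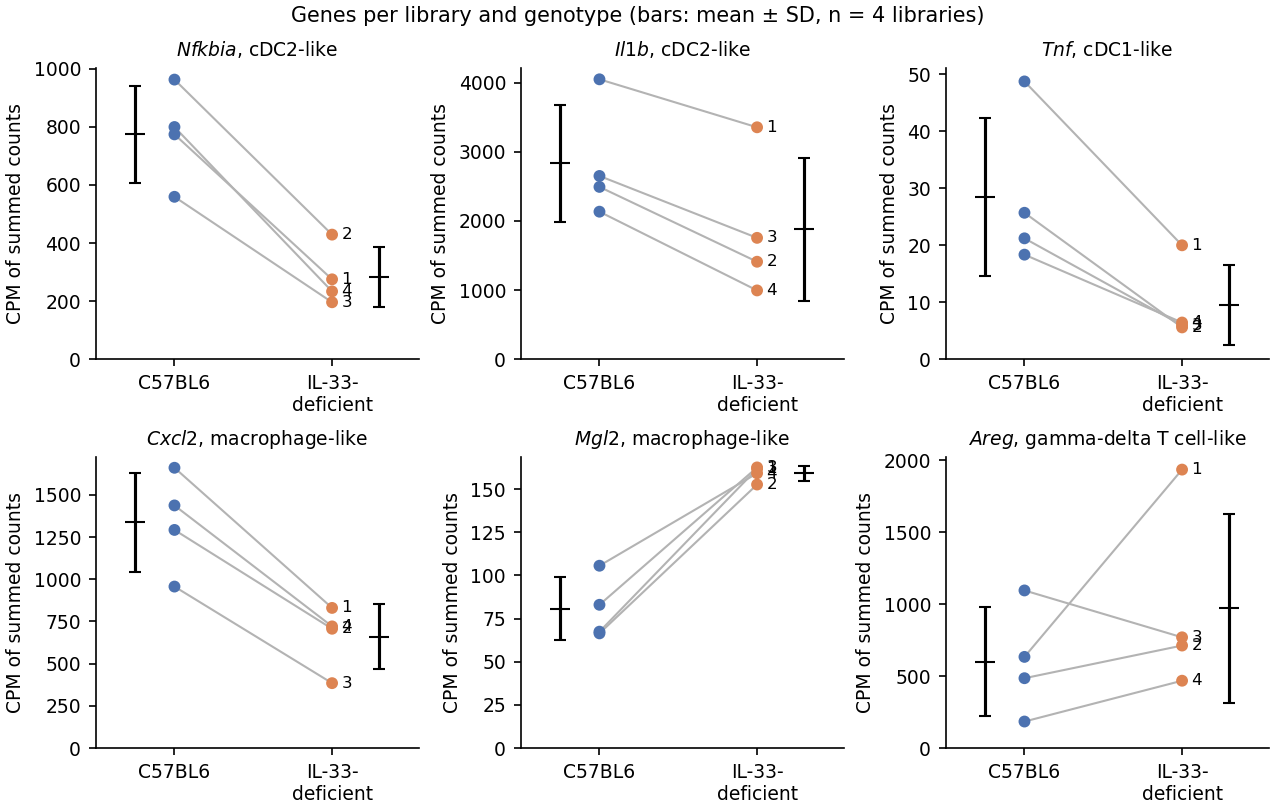
Level of Nfkbia, Il1b, Tnf, Cxcl2, Mgl2 and Areg in CPM per library and genotype, each panel for 1 gene and class, with numbered points for the libraries, lines joining the genotypes of a library and bars for the mean ± SD. Il1b in cDC2-like and Areg in gamma-delta T cell-like cells did not pass, whereas the other 4 genes did.

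Across all 12 classes, 24 calls were rises and 63 falls, 87 in all. The excess of falls was smaller without the filter on low counts (200 rises and 221 falls), without library 3 (96 and 102) and without library 2 (38 and 43). In all 126 list tests were made over these classes and all cells together. Fry passed for 4 tests, those of inflammation in cDC2-like cells, of type I interferon and interferon-gamma in B cell-like cells, and of glycolysis and hypoxia in cluster 5. In the last, all 12 members lay below 0 with a median of -0.155 (fry adjusted p = 0.0397), Gapdh, a glycolysis gene, had a log2 change of -0.17, and camera did not pass (0.0705, adjusted p = 0.555 with an estimated correlation). Camera passed in 47 tests, of which 3 also passed fry and 1 remained with an estimated correlation, inflammation in cDC2-like cells. PValue.Mixed of fry passed in 9 tests, which also included alternative activation (0.0385) and immediate-early genes (0.0452) in cDC2-like cells and the type I interferon (0.00453) and interferon-gamma (0.00224) lists in non-classical monocyte-like cells, where Isg15 differed by 0.67 ± 0.18 (edgeR adjusted p = 0.964).

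Other lists did not pass the PValue of fry, which tests for 1 direction, in any class, although camera passed for some of them. Type 2 cytokines and IL-33 receptor could be tested in all cells only, where 4 of 7 members lay above 0, none passed and 2 were higher when adjusted over the list alone (median 0.39, fry adjusted p = 0.736). The lowest fry adjusted p was 0.255 for tissue remodelling and angiogenesis (7 tests, cDC2-like, where Fn1 had a log2 change of 0.68 ± 0.15, edgeR adjusted p = 0.146), 0.569 for eosinophil and monocyte chemoattractants (2 tests, macrophage-like, Ccl2 at -0.06 ± 0.10), 0.569 for the resident macrophage programme (3 tests, macrophage-like, 7 of 7 above 0) and 0.447 for the lipid-associated programme (12 tests, NK or ILC1-like). It was 0.176 for NK granules and ligands (11 tests, B cell-like), 0.2 for MHC class II presentation (11 tests, macrophage-like), 0.612 for the cell cycle (8 tests, cDC2-like, 14 of 15 below 0), 0.612 for the regulatory T cell programme (6 tests, cDC2-like) and 0.176 for immediate-early genes (13 tests, B cell-like). Alternative activation did not pass the PValue of fry in any of 4 tests, whereas PValue.Mixed passed in 2 and camera in 3, and Ctla4, a regulatory T cell gene, differed by 0.58 ± 0.43 in T cell-like cells. The median and the fry direction had opposite signs for the lipid-associated list in T cell-like, cDC2-like and non-classical monocyte-like cells, for immediate-early genes in T cell-like cells, cluster 5 and mature DC-like cells, and for NK granules in T cell-like cells and cluster 5. They also did for MHC class II in B cell-like, remodelling in classical monocyte-like, regulatory T cell genes in gamma-delta T cell-like, cell cycle in macrophage-like, inflammation and type I interferon in neutrophil-like cells, and chemoattractants in all cells, where the lipid-associated list was down by fry and up by camera.

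The share of cells per class showed 0 differences past the threshold in 22 tests by edgeR, with 2 at an unadjusted p under 0.05, and no second tool was run for shares. Cluster 20, with Cxcr6 and Rora among its leading genes, made up 0.64% ± 0.463 of C57BL6 and 2.53% ± 1.95 of IL-33-deficient cells (log2 ratio 1.83 ± 0.58 SE, edgeR adjusted p = 0.189, higher in 4 of 4 libraries, with the smallest exact sign-flip permutation p that 4 libraries allow). Neutrophil-like cells made up 2.39% ± 1.84 and 5.28% ± 2.32 (1.33 ± 0.52, edgeR adjusted p = 0.289, higher in 3 of 4, exact sign-flip permutation p = 0.25). Gamma-delta T cell-like cells made up 3.6% ± 4.36 and 6.13% ± 4.8 (1.10 ± 0.53, edgeR adjusted p = 0.446, higher in 3 of 4). Macrophage-like cells made up 4.19% ± 1.76 and 2.7% ± 0.49 (-0.57 ± 0.38, edgeR adjusted p = 0.696, lower in 4 of 4), and NK or ILC1-like cells 51.5% ± 8.84 and 44.4% ± 4.81 (-0.21 ± 0.36, edgeR adjusted p = 0.837). Cluster 20 passed without library 1 (2.13, edgeR adjusted p = 0.025) or library 2 (2.29, 0.0308), with a stricter cell filter (1.98, 0.0229) and in shares without neutrophil-like cells (1.89, 0.0271), and neutrophil-like cells without library 1 (1.92, 0.025). Libraries 3 and 4 carried the cluster 20 difference, with 0.251% and 3.64% in library 3 and 1.1% and 4.63% in library 4, against 0.228% and 0.37% in library 1 and 1.02% and 1.47% in library 2. In library 3 it came with rises of other classes that were more common in C57BL6 cells of libraries 2 and 4. There gamma-delta T cell-like cells made up 0.613% and 3.62%, cluster 5 0.975% and 4.14%, and cluster 13 2.09% and 8.48%. Not all such classes rose, as with cDC2-like (3.48% and 3.4%) and macrophage-like cells (2.79% and 2.66%). The cause of this joint shift in library 3 was not tested. Without library 3 or 4 the cluster 20 ratio was 1.20 and 1.68 (edgeR adjusted p = 0.367 and 0.605), and the neutrophil-like ratio without library 4 was 0.88 (0.605). Under the ratio rule for hashtags basophil-like cells passed as lower in 4 of 4 libraries (-2.51, edgeR adjusted p = 0.0334, 44 cells), against a log2 ratio of 0.57 over 13 cells without it (edgeR adjusted p = 0.837). That rule took the NK or ILC1-like share of C57BL6 cells in library 2 from 45.0% to 59.0%. With it NK or ILC1-like cells were lower and gamma-delta T cell-like cells higher in 4 of 4 libraries, though neither passed (edgeR adjusted p = 0.723 and 0.0904). ILC2-like cells, a class with high Il1rl1, numbered 74 and made up 0.333% ± 0.385 and 0.323% ± 0.352. Live CD45.2+ sorting, dead cell removal and unassigned cells, 28.0% of barcodes in library 2, can set these shares.

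**Figure D4:**
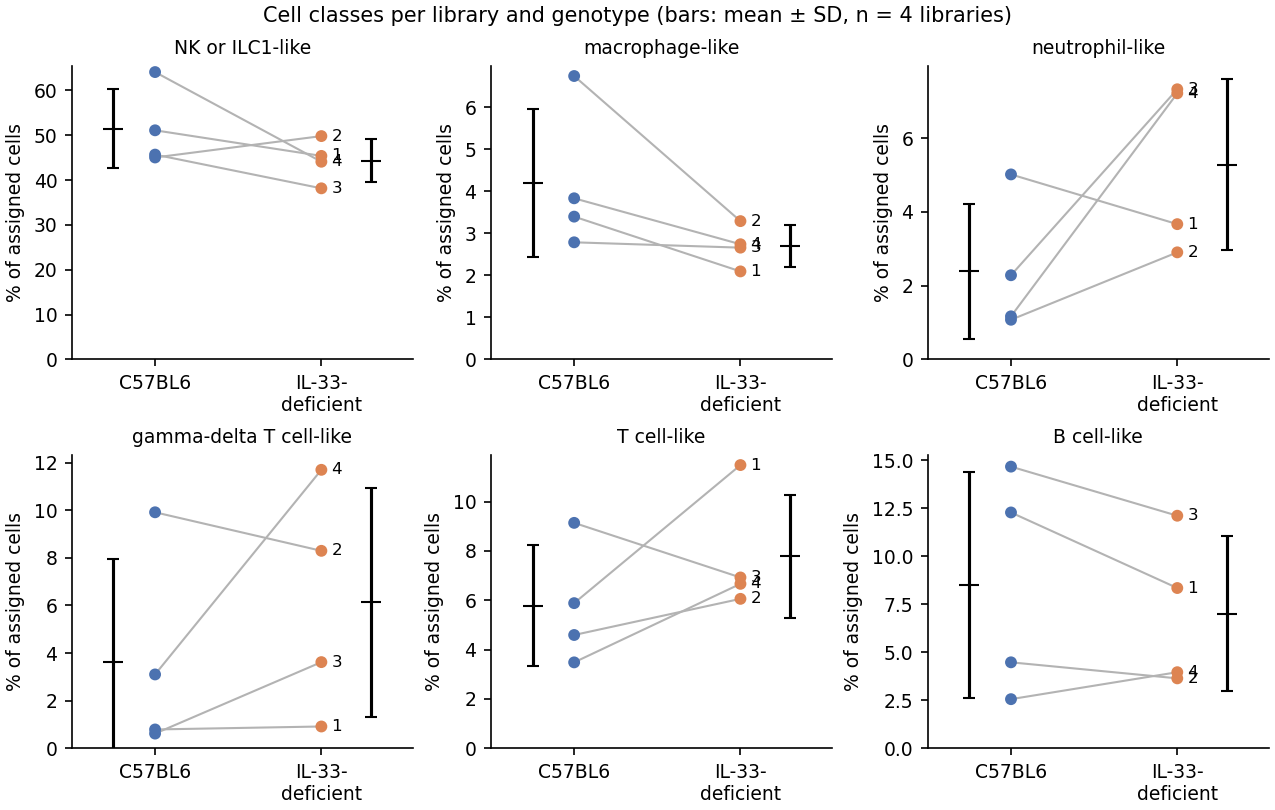
Share of cells per class in percent, with 1 numbered point per library and genotype and bars for the mean ± SD of 4 libraries, the lower end stopping at 0. Neutrophil-like cells had means of 2.39% and 5.28%, and macrophage-like cells 4.19% and 2.7%, in C57BL6 and IL-33-deficient cells.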

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

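The tests of strain variants with their windows and shuffles, of hashtag assignment, of depth, of handling and of the splits were chosen after the results were seen, whereas the ratio rule and thinned cells that they draw on, the list tests and the tests of neutrophil RNA and of another mixture of cells were planned or written before.

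In 17 of 212 tested groups of 4 libraries (8.02%) 1 sample lay far from the other 3, where chance gives about 1 in 20. Among levels in C57BL6 cells, Mpp7 was at 45.4 CPM in NK or ILC1-like cells of library 4 (35.5 to 36.1 in the others) and at 66.3 CPM in T cell-like cells of library 2 (30.2 to 30.9). AC149090.1 was at 91.1 CPM in T cell-like cells of library 1 (196 to 199) and Spp1 at 735 CPM in macrophage-like cells of library 1 (114 to 174). In IL-33-deficient cells of library 1, Spp1 was at 501 CPM (76.6 to 119) and Arg1 at 142 CPM (12.6 to 29.5) in macrophage-like cells. The same sample had Tnf at 20 CPM in cDC1-like (5.61 to 6.47), Gzme at 461 CPM in cluster 5 (0.896 to 63.3), Mpp7 at 24.8 CPM in gamma-delta T cell-like (0.951 to 2.55) and Ide at 43.2 CPM in NK or ILC1-like cells (58.8 to 60.7). Hspa1b was at 490 CPM in IL-33-deficient non-classical monocyte-like cells of library 4 (104 to 129).

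Among shares of C57BL6 cells, cDC2-like cells made up 7.31% in library 2 (3.48% to 4.02% in the others), and clusters 11 and 24 made up 2.87% (0.0567% to 0.304%) and 1.64% (0.0544% to 0.127%) in library 3. Among IL-33-deficient cells, T cell-like cells made up 11.5% in library 1 (6.06% to 6.92%), and in library 3 cluster 24 made up 2.2% (0.037% to 0.175%) and mature DC-like cells 0.24% (0.518% to 0.566%). The 3627 cells without a genotype, which entered no comparison in the main setting, held 1.27% basophil-like, 0.744% epithelium-like, 0.772% fibroblast-like and 1.68% endothelium-like cells, against 0.0486%, 0.0299%, 0.0336% and 0.142% of compared cells. Of those classes 78%, 77.1%, 75.7% and 61.6% of cells had no genotype. Some of these cells were compared under the ratio rule, which held 44 basophil-like cells instead of 13.

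Of 10 genes called in more than 1 class, Mpp7 was lower in 9 of 9 and Wdfy1 higher in 7 of 7 classes that tested them, and called genes gathered near Il33 on chromosome 19 (12.6 times the share of all tested genes) and in the first 15 Mb of chromosome 18 (29.1 times, in a window drawn around them). Under the ratio rule for hashtags 91.4% of the calls made in more than 1 class stayed, so most did not hinge on the choice of rule. Because that rule reads the same tag counts, it cannot expose wrong tags, and hashtag assignment stays open. With cells thinned to the same depth a median of 96.6% of the change in these calls stayed. Thinning keeps the expected share of each gene in a cell's UMIs, so little loss was likely in any case. This value therefore cannot decide on depth, which stays open. The windows are consistent with a strain variant carried with the targeted allele, for chromosome 19 as DNA linked to Il33 and for chromosome 18, where none of the shuffles of the calls gave as extreme a window anywhere (permutation p = 0.001), as a separate segment, but no sequence was compared. Wdfy1 (chromosome 1) and Mid1 (chromosome X) lie in neither window. An effect of IL-33 on these genes stays open, since no control with the flanking DNA but intact Il33 is in the series.

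Inflammation genes lay lower in cDC2-like cells (median -0.717), led by Nfkbia. Handling that raises immediate-early genes such as Fos and Jun along with inflammation genes is argued against there as the whole cause, since their median was -0.186 (SD 0.249 over members), and -0.15, -0.047, -0.112 and -0.411 in libraries 1 to 4, but a part of it stays open, as 11 of 14 lay below 0, PValue.Mixed of fry passed (adjusted p = 0.0452) and Jun and Egr1 were called lower (-0.39 and -0.70, edgeR adjusted p = 0.0375 and 0.00284). In cDC1-like cells the immediate-early median was 0.144, which met the rule set against handling as the whole cause. The inflammation median there was only -0.238, at -0.101, -0.334, -0.37 and -0.003 in libraries 1 to 4, and fry did not pass in 1 direction. With so small a fall the rule decides little in these cells. In macrophage-like cells (0.037) handling cannot be told apart, because the inflammation median there was only -0.139. RNA from neutrophils, a source of Il1b and Cxcl2, cannot be told apart either, as S100a8 and S100a9 differed by a mean of 1.24 in cDC2-like cells but by -0.462, -2.619, 5.696 and 2.335 in the 4 libraries. Another mixture inside the class stays open because the only finer cluster with enough cells (median -0.688) holds 97.2% of it, and an effect of IL-33 deficiency, which is what the design varies, stays a hypothesis that giving IL-33 back to such dams could test.

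For the counts of called genes, the 8 splits that part both genotypes of every library are too few for a share under 0.05. The number of splits with as many genes as the real one, itself included, was 1 in all cells (7 genes, 1 in the highest other split), B cell-like (5, 2), NK or ILC1-like (11, 5), cDC1-like (12, 5), cDC2-like (30, 6) and gamma-delta T cell-like cells (6, 1). It was 2 in T cell-like (5, 49), macrophage-like (10, 14) and neutrophil-like cells (1, 7), 3 in classical monocyte-like cells (5, 17), 5 in cluster 5 (2, 2), and 8 in mature DC-like (0, 6) and non-classical monocyte-like cells (0, 4), for which edgeR gave 98 and 137 genes at an unadjusted p under 0.05 and DESeq2 0. Splits that call several times the real count point to a structure of the samples, which no test here identifies. They swap the genotypes of libraries 3 and 4 in T cell-like and classical monocyte-like cells and of library 3 in neutrophil-like cells. Where the real count is 0, any split has as many, so the splits say nothing about mature DC-like and non-classical monocyte-like cells.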

How the results depend on the processing

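The analyses without chromosomes 18 and 19, the clustering without called genes and the clusterings at seeds 1 and 2 were chosen after the data had been seen, and the other alternatives were planned. Where a result changed, the cause was not tested unless stated.

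Among the 78 named gene calls, all 78 stayed with DESeq2 size factors or without a filter on low counts, as did 73 of 73 with at least 30 cells per sum. The number was 65 with the ratio rule for hashtags, 70 with scrublet calls kept, 65 of 76 with the stricter cell filter, 48 of 56 without chromosomes 18 and 19, 42 by DESeq2, 20 of 48 with cells thinned to 1000 UMIs and 9 without the library block. It was 59 of 74, 42 of 76, 57 of 75 and 46 of 77 without libraries 1 to 4. Named genes kept their sign throughout except Klf4 in cDC1-like cells, which went from 0.58 to -0.10 with cells thinned to 1000 UMIs. The largest rises and falls were named only with 1 sign in every library. Their kept signs with a library left out were therefore largely set in advance. Over all values of named genes 941 kept their side of the threshold, 296 lost it and 5 gained it.

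The clustering itself was a source of change. At seeds 1 and 2, 58 of 71 named calls stayed in each case. Nfkbia, Nfkbiz and Icam1 in cDC2-like cells kept their calls at both seeds, as did Cxcl2 and Dusp2 in macrophage-like and Gem in gamma-delta T cell-like cells. Calls that ended included Tnf in cDC2-like cells at seed 1 (edgeR adjusted p = 0.133), Egr1 there at both seeds (0.519 and 0.163), Nfkbia in macrophage-like cells at seed 2 (0.472), Arg1 there at both seeds (1 and 0.48), and Areg (0.0564 and 0.106) and Ikzf2 (0.396 and 0.511) in T cell-like cells. The cDC2-like inflammation list had a fry adjusted p of 0.0589 at seed 1 and 0.0158 at seed 2. Counts at seed 1 were 8 in B cell-like, 3 in T cell-like, 8 in classical monocyte-like and 1 in non-classical monocyte-like cells, and at seed 2 they were 8 in B cell-like and 1 in T cell-like cells.

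At seeds 1 and 2 the count was 83 and 88 over 11 classes, without cluster 5, which gave 2 of the 87 calls over 12 classes. That count of 87 was 91 with DESeq2 size factors, 65 by DESeq2, 89 with the ratio rule, 89 with the stricter filter, 92 with scrublet calls kept and 59 without chromosomes 18 and 19, and it was 111 with at least 30 cells over the 10 classes that had them. It was 421 without a filter on low counts, 35 with thinned cells, 8 without the library block and 75 to 198 with 1 library left out. Falls outnumbered rises in each of these, most narrowly with 221 against 200 without the filter, 102 against 96 without library 3 and 43 against 38 without library 2. Without that filter the count was 31 in all cells, 16 in B cell-like, 37 in NK or ILC1-like, 24 in T cell-like, 30 in cDC1-like, 138 in cDC2-like, 27 in classical monocyte-like, 17 in cluster 5, 39 in gamma-delta T cell-like, 56 in macrophage-like, 11 in mature DC-like, 13 in neutrophil-like and 13 in non-classical monocyte-like cells. Without the library block it was 1 in all cells, NK or ILC1-like, cDC1-like, cDC2-like, gamma-delta T cell-like and macrophage-like cells, 2 in classical monocyte-like cells, and by edgeR 0 in B cell-like and T cell-like cells and cluster 5. Dropping the block leaves the spread between libraries in the error.

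By DESeq2 the count was 54 in all cells, 1 in B cell-like, 21 in NK or ILC1-like, 1 in T cell-like, 3 in cDC1-like, 3 in classical monocyte-like, 2 in gamma-delta T cell-like and 2 in neutrophil-like cells and 0 in cluster 5. The ratio rule gave 24 in all cells, 13 in B cell-like, 1 in T cell-like and 10 in gamma-delta T cell-like cells and 5 in cluster 5. The stricter filter gave 3 in T cell-like and 1 in mature DC-like cells, scrublet calls kept gave 10 in B cell-like cells and 4 in cluster 5, and at least 30 cells gave 28 in cDC1-like and 14 in gamma-delta T cell-like cells. Thinned cells gave 12 in all cells, 14 in cDC2-like, 2 in classical monocyte-like, 1 in macrophage-like and by edgeR 0 in cDC1-like, T cell-like and neutrophil-like cells and cluster 5. Without chromosomes 18 and 19, which removes Mpp7, Npc1 and Colec12 from the test, it was 1 in all cells, 3 in NK or ILC1-like, 1 in classical monocyte-like and 0 in T cell-like and neutrophil-like cells by edgeR.

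With 1 library left out, counts ranged from 0 to 11 in all cells, 3 to 17 in B cell-like, 6 to 25 in NK or ILC1-like, 1 to 5 in T cell-like, 6 to 28 in cDC1-like, 18 to 70 in cDC2-like, 4 to 57 in classical monocyte-like, 2 to 4 in cluster 5, 1 to 14 in gamma-delta T cell-like, 5 to 13 in macrophage-like, 0 to 1 in mature DC-like and 1 to 4 in neutrophil-like cells. The classical monocyte-like and cDC2-like maxima of 57 and 70 came without library 3.

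Of 3 list tests that passed both fry and camera, 1 remained with an estimated correlation, 0 by fry without the library block, and 0 to 2 with 1 library left out. Type I interferon genes such as Isg15 in B cell-like cells had adjusted p = 0.0887 with an estimated correlation, 0.87 without the block and 0.0312 to 0.0867 with library 2 or 4 left out. Interferon-gamma genes there had adjusted p = 0.124 with an estimated correlation, 0.0897 without the block, 0.168 without chromosomes 18 and 19 and 0.0148 to 0.564 with 1 library left out. The cDC2-like inflammation list had 0.0866 without the block and 0.155 to 0.353 with 1 library left out, where fewer samples remain.

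Class shares passed in 1 case each with the ratio rule (basophil-like cells), the stricter filter and without neutrophil-like cells (both cluster 20), and in 0 to 2 cases with 1 library left out. Cluster 20 had a log2 ratio of 1.98 with the stricter filter, 1.89 without neutrophil-like cells and 1.20 to 2.29 with 1 library left out, and neutrophil-like cells 0.88 to 1.92. Of 305 other share values 276 kept their sign and their side of the threshold, 5 passed with the same sign and 24 changed sign, of which only the basophil-like share under the ratio rule passed. Small ratios changed sign with 1 library left out in B cell-like (-0.38 to 0.013), ILC2-like (-0.17 to 0.71), basophil-like (-0.078 to 1.70), cDC1-like (-0.54 to 0.01), cDC2-like (-0.062 to 0.081), classical monocyte-like (-0.15 to 0.27), fibroblast-like (-0.043 to 1.76), mast cell-like (-0.72 to 0.73) and non-classical monocyte-like cells (-0.39 to 0.008) and clusters 11 (-0.10 to 0.85) and 24 (-0.047 to 0.34). The ratio rule turned basophil-like (-2.51), fibroblast-like (-0.92) and cluster 11 (-0.41) shares, the stricter filter fibroblast-like (-0.073) and no block ILC2-like shares (-0.035). The cDC2-like ratio of 0.02 became -0.083 with TMM over classes and -0.007 and -0.026 at seeds 1 and 2. The classical monocyte-like ratio of 0.06 became -0.04 with TMM over classes, -0.01 at resolution 2.0, -0.041 in the clustering without called genes and -0.044 at seed 1.

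Some alternatives gave no value. Arg1 in macrophage-like cells was not tested without library 1, Mid1 there without library 2, Isg15 and Ifit3 in B cell-like cells and Gzme in cluster 5 without library 1 or 3, and AA467197 in gamma-delta T cell-like cells without library 2 or 4. Unnamed clusters have none at other resolutions or seeds, mature DC-like and non-classical monocyte-like cells none at 30 cells, cDC2-like shares none at resolutions 0.5 and 2.0, and the type I interferon list of B cell-like cells none without library 1 or 3. Comparisons of the tissues under other settings were not run because no matrix could be tied to a tissue. With thinned cells the count over the classes fell from 87 to 35, whereas the count in all cells together rose from 7 to 12. In simulated data a log2 change of 1 was recovered for 24% of planted genes in neutrophil-like and 43% in mature DC-like cells, and how much of this is due to depth was not tested, since neutrophil-like cells also had the largest spread between sums (common biological coefficient of variation 0.292 by edgeR). Both rates can overstate the recovery of real changes, as many other changes were planted beside them.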

Other observations

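The values in this part belong to no comparison, were chosen after the data had been seen, and are given per library without an explanation. Libraries 1 and 3 resembled each other in several readouts, as did libraries 2 and 4. Residuals from the genotype means correlated at r = 0.795 and 0.753 between libraries 1 and 3, and at 0.805 and 0.841 between libraries 2 and 4.

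In NK or ILC1-like cells of both genotypes together the granzyme gene Gzmd was at 14800, 288, 9737 and 1620 CPM in libraries 1 to 4, Gzme at 6892, 148, 4617 and 668 CPM, and Gzmb at 5806, 1498, 4925 and 2246 CPM. The angiogenic factor gene Vegfa was at 26.8, 160, 28.1 and 157 CPM in the same cells. In cDC2-like cells Retnla, a gene of alternative activation, was at 45.2, 2108, 212 and 2017 CPM, and Il1rl1 at 5.96, 63.4, 10.4 and 45.3 CPM. Apoe in macrophage-like cells was at 19820, 12960, 16770 and 12410 CPM, and Areg in gamma-delta T cell-like cells at 1275, 619, 727 and 383 CPM.

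Of C57BL6 cells, classical monocyte-like cells made up 10.3%, 3.17%, 12.1% and 1.39% in libraries 1 to 4, B cell-like cells 12.3%, 4.48%, 14.7% and 2.56%, cDC1-like cells 1.39%, 6.52%, 0.808% and 4.89%, and gamma-delta T cell-like cells 0.786%, 9.92%, 0.613% and 3.1%. ILC2-like cells made up 0%, 0.623%, 0% and 0.707%. They had enough cells for a level in libraries 2 and 4 only, where Areg was at 552 and 769 CPM, Il5 at 234 and 230 CPM, Arg1 at 310 and 332 CPM and Calca at 492 and 275 CPM.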
